A study of Homo sapiens with 34 samples.

How the data were processed

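Processed data were 34 peak lists, 1 per library, on hg38. Per the submitters' processing notes, Trim Galore 0.6.6, Bowtie2 2.3.5, SAMtools, bedtools and MACS2 2.2.7.1 were used, with no role or order given. Peaks were called per library, since each deposited list carries the peak names of 1 library. The names given to the deposited lists state an FDR of 0.001 and the removal of blacklisted regions, and the smallest -log10 q-value in the authors' lists lay just above 3. Whether a control library was used and how duplicates were treated is not given in the sources used here.

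Each deposited list gives a start and end, a display score, a fold enrichment, and -log10 of a p-value and a q-value for each peak. The score is the authors' rounded multiple of -log10 q and was not used further. The fold is the authors' ratio of the summit to the local background that MACS2 estimated in the same library. The -log10 p and -log10 q columns are the authors' Poisson p-values before and after adjustment. These values belong to each peak, and were used to rank and filter peaks within a list.

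Read totals were not used here, so depth is unknown. Whole numbers of fragments at the summit were recovered from the fold and the p-value, with a tolerance of 0.0005 in -log10 p, for at least 99.95% of the 1993 to 2328 peaks sampled per library. The lowest local background so recovered was 0.164 to 0.405 fragments in PC3 DM libraries and 0.501 to 0.872 in COLO320 DM libraries. It rises with depth and copy number and is not scaled between libraries.

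Groups and replicate numbers came from the sample titles. Nothing says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Autosomes and the X chromosome were used. The gene table was RefSeq on GRCh38.p14, the same build as hg38, and gave neither strand nor exons. The region first chosen, the gene body and 2 kb before it, was therefore replaced by the gene and 2 kb on each side, and a comparison around the transcription start by 2 kb around either gene end. Exon, intron and UTR positions are not given for that reason.

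The percentage of peaks in the window around MYC and log10 of the number of peaks were compared with two-sided exact permutation tests. The presence of a peak in each 5 kb bin, and in each protein-coding gene, was compared with Fisher's exact test, two-sided, on bins or genes with at least 3 libraries with and 3 without a peak. Benjamini-Hochberg adjustment was made over the tested bins or genes, at a threshold of 0.05. Gene lists, 14 in all, were compared by the percentage of members with a peak per library, with 100000 resamples between lines and exact permutation within a line. Comparisons of the same line share the combination libraries and most other libraries, so they are not independent. The comparison of each single perturbation assumed that the combination includes it, which the labels do not state.

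Named genes were chosen by a rule fixed before the data were examined: the 12 per direction with the largest difference in the share of libraries, 2 from each list with 2 or more calls, and MYC, PVT1, CDX2 and PDX1. PVT1 is not protein-coding and appears by its covered length. Named bins were the 5 with the smallest p in each comparison. The bins among the 100 best peaks, and the totals over MYC, LRATD2 and PVT1, were chosen after their values were seen.

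Other settings fixed in advance were q-values of 1e-05 or less (-log10 q of at least 5), lists of equal length, the covered length in place of the number of peaks, a window of 1 Mb, bins of 10 kb, an overlap of 500 bp, the combination left out, tests within replicate numbers, vector libraries alone and each replicate left out. Added after seeing the data were the 50, 100, 200, 300 and 1000 best peaks, a window of 10 Mb, genes without flanks, gene ends, and leaving out the 2 lists with over 100000 peaks. Ranking was by q-value, then fold.

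The tests were tested on simulated data. In the gene comparison, of 10067 genes 200 were changed: 100% of 100 with complete separation and 39% of 100 with a difference of 60 points were recovered, and 14 of 9867 unchanged genes were called. In the bin comparisons 20 bins were changed, because 123 to 184 were tested: 100% of complete separations were recovered in each, and from 0 to 50% of differences of 60 points. The 100% was fixed in advance, since in these comparisons 1 completely separated bin is enough to pass. Planting 10 of them also eased the adjustment for the smaller differences. Bins over the whole genome on the lists as deposited were not simulated. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.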

Results

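CUT&Tag, in which an antibody directs a transposase to marked chromatin, was run with a rabbit antibody that the labels call anti-H3K9me, without the degree of methylation. The cells were PC3 DM, from a prostatic adenocarcinoma, and COLO320 DM, from a colorectal adenocarcinoma. In both lines the oncogene MYC is carried on extrachromosomal DNA (ecDNA), circles outside the chromosomes. Each library came from 50000 nuclei taken 3 days after transfection of 700 ng of sgRNA plasmid. The plasmids were an empty vector, single perturbations named ecSE and a number, and a combination named ecSEcombo. PC3 DM had 16 libraries: 2 for the vector, 3 each for ecSE1, ecSE2 and ecSE6, 2 for ecSE7 and 3 for the combination. COLO320 DM had 18 libraries, 3 each for the vector, ecSE1, ecSE2, ecSE3, ecSE4 and the combination. The labels give neither the genome positions of these elements nor what the combination covers, and do not say whether an element of the same name is the same DNA in both lines.

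The authors' lists held 36008 ± 23610 peaks per library in PC3 DM (SD, n = 16) and 25454 ± 25519 in COLO320 DM (SD, n = 18), from 9385 to 125214. The longest lists were COLO320 DM ecSE1 replicate 2, with 125214 peaks, and PC3 DM ecSEcombo replicate 1, with 102290. Perturbed and vector libraries did not differ detectably in log10 peaks (difference -0.033 in PC3 DM, exact permutation p = 0.967, and 0.153 in COLO320 DM, exact permutation p = 0.196). Read totals are unknown, so no counting interval is given. Libraries of the same group shared a median of 4.80% of the 1 kb bins that either of a pair covered in PC3 DM and 17.8% in COLO320 DM, against 4.53% and 18.1% for other groups of the same line. Pairs of different lines shared 4.55%, about as much as PC3 DM libraries shared with each other, and no pair looked like a library deposited again. COLO320 DM ecSE1 replicate 2, with the longest list, stood apart: it shared from 4.17% to 7.77% with the others of its line, median 6.22%, where the medians of the other 17 libraries ran from 12.3% to 22.2%.

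The first question was whether directing the perturbations to ecDNA elements changed the share of peaks that lay around MYC. This share counts peaks and does not measure how much of the mark they hold. On hg38 the window ran 2 Mb to each side of the lower end of MYC, chromosome 8 from 125735434 to 129735434. In COLO320 DM vector libraries 2.84% ± 1.05 of all peaks lay in it (SD, n = 3), and in PC3 DM vector libraries 0.260% ± 0.021 (SD, n = 2). Perturbed libraries had 2.08% ± 0.62 in COLO320 DM (n = 15) and 0.289% ± 0.0552 in PC3 DM (n = 14). Neither difference exceeded the spread between libraries (-0.760 points, exact permutation p = 0.113, and 0.0288 points, exact permutation p = 0.533). By number, 423 ± 45.5 peaks lay in the window with the vector and 446 ± 116 in perturbed libraries of COLO320 DM. In PC3 DM these were 93.5 ± 60.1 and 96.9 ± 59.4. The share was 0.667% in the longest COLO320 DM list and 3.95% in the shortest, so it cannot be read apart from list length.

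**Figure D1:**
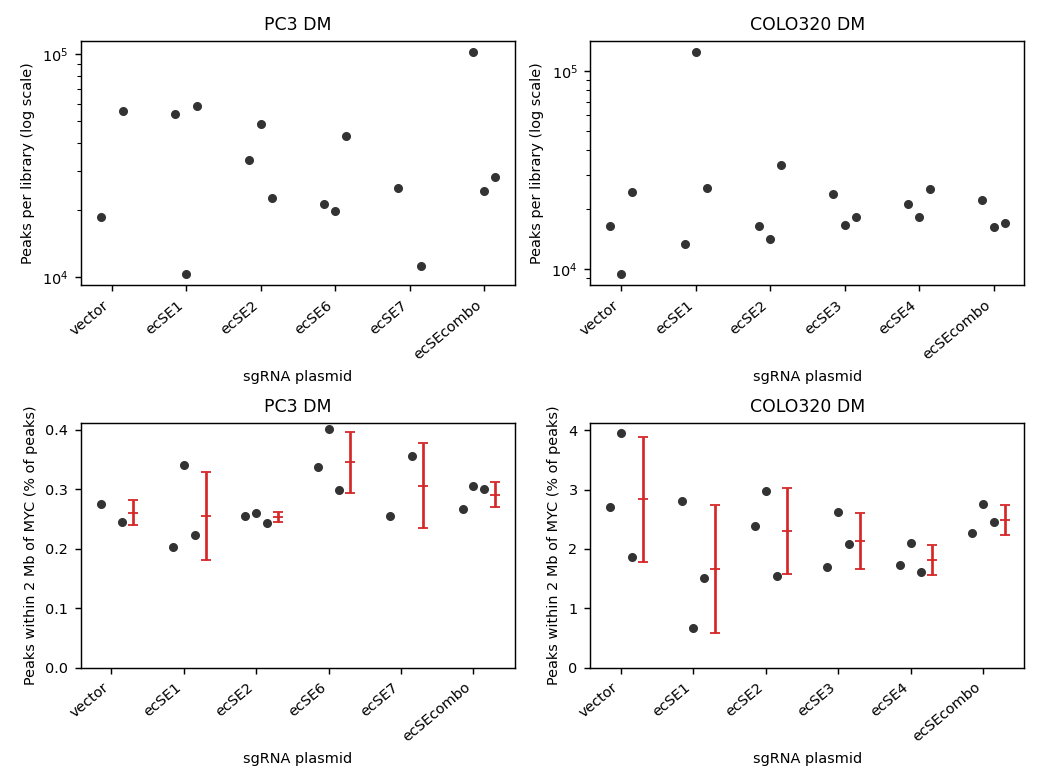
Peaks per library on a log axis (top) and the percentage of a library's peaks within 2 Mb of MYC (bottom) for each sgRNA plasmid in PC3 DM and COLO320 DM. Points are libraries and red bars are the mean ± SD of a group; most groups overlap, the 3 ecSE6 libraries of PC3 DM lie above both vector and all 3 ecSE2 libraries, and COLO320 DM lies between 0.667% and 3.95% against 0.203% to 0.400% in PC3 DM.

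Among single plasmids, the ecSE6 libraries of PC3 DM had 0.345% ± 0.0516 of their peaks around MYC (n = 3), 0.0850 points above the vector (exact permutation p = 0.2). The ecSE4 libraries of COLO320 DM had 1.81% ± 0.251 (n = 3), 1.03 points below the vector (difference -1.03, exact permutation p = 0.2). No plasmid passed, and none could have: the smallest two-sided p is 0.1 for 3 libraries against 3, 0.2 for 3 against 2 and 0.333 for 2 against 2. The effect of the combination differed between the lines by -0.380 points (permutation within lines, p = 0.665). These 15 tests gave Benjamini-Hochberg adjusted p of 0.75 or more.

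Within the window, 5 kb bins were compared between the libraries of a single perturbation together with the combination and all other libraries of the line. In COLO320 DM, ecSE3 brought peaks to the start of PVT1, a long non-coding RNA gene beside MYC (127794524 to 128101256). The bin 127790001 to 127795000 had a peak in 6 of 6 libraries against 0 of 12, covering 1554 ± 325 bp against none (Fisher exact test, adjusted p = 0.00711). The next bin, 127795001 to 127800000, which also holds MIR1204, had a peak in 6 of 6 against 1 of 12 libraries and 3038 ± 478 bp against 20.8 ± 72.2 bp (Fisher exact test, adjusted p = 0.0249). With ecSE2, the bin 126550001 to 126555000 at LRATD2 had a peak in 6 of 6 against 1 of 12 libraries, covering 1141 ± 416 bp against 34.2 ± 118 bp (Fisher exact test, adjusted p = 0.0498). With ecSE4, the bin 127730001 to 127735000 in CASC11, which ends just before MYC, had a peak in 0 of 6 against 11 of 12 libraries, where it covered 802 ± 391 bp on average (Fisher exact test, adjusted p = 0.0498).

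With ecSE1, no bin of COLO320 DM passed (Fisher exact test, smallest adjusted p = 0.299), although 7 of the 132 tested had an unadjusted p under 0.05. The bin 127245001 to 127250000 in CASC21 had a peak in 6 of 6 against 3 of 12 libraries, covering 4026 ± 72.8 bp against 84.6 ± 156 bp. In PC3 DM, 184 bins were tested and none passed for ecSE1, ecSE2, ecSE6 or ecSE7 (Fisher exact test, 9, 12, 14 and 4 with an unadjusted p under 0.05). For ecSE1 and ecSE2 of PC3 DM, the bins called below among the best peaks lie outside the window. Neither this test nor the share of peaks around MYC covers those bins. With ecSE6 the bin 127800001 to 127805000 in PVT1 had a peak in 5 of 6 against 0 of 10 libraries (Fisher exact test, adjusted p = 0.253). Over the whole genome 0 of 37638 bins passed in COLO320 DM and 0 of 62247 in PC3 DM in any comparison (Fisher exact test, 301 to 954 and 668 to 3194 with an unadjusted p under 0.05). Few libraries largely set these 0s: with a single perturbation and the combination, at least 41 bins in COLO320 DM and 156 in PC3 DM had to reach the smallest possible p for 1 to pass, and at most 1 and 4 separated the libraries completely. The call at LRATD2 was lost when any library except ecSE1 replicate 2 was left out, and the call at CASC11 when any except ecSE1 replicate 1 was. Both were also lost in a 10 Mb window and within replicate numbers, where 1 bin at the smallest p is enough to pass. At PVT1, 1 of the 2 calls was lost in these settings and without any single ecSE3 or combination library. Without the combination 5 bins at the smallest p are needed, so neither could pass, but 1 bin still separated the 3 ecSE3 libraries from the 12 others.

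Lists of very different length make the presence of a weak peak uninformative, so the 100 best peaks of each list by q-value were compared genome-wide, a choice made after seeing the data. Such ranks depend on list length and by themselves show no change in the mark. In COLO320 DM this was mostly a test of the window around MYC. There 63 to 76 of each 100 peaks lay within 2 Mb of MYC, as did 81 of the 123 tested bins. In PC3 DM 3 to 14 peaks and 7 of 138 tested bins did. With ecSE1 in COLO320 DM 4 bins passed, all in or beside CASC21 between 127230001 and 127255000. With ecSE2 there were 3 in CASC8 between 127395001 and 127410000, a stretch that holds CCAT2. With ecSE3 there were 2 at the start of PVT1 between 127790001 and 127800000. With ecSE4 5 passed: MYC itself at 127735001 to 127740000 and 127740001 to 127745000, CASC11 at 127725001 to 127730000, PVT1 at 127820001 to 127825000 and LOC105375751 at 126690001 to 126695000. Each of these 14 bins held 1 of the 100 best peaks in 6 of 6 libraries, against at most 2 of 12 others (Fisher exact test over 123 bins, adjusted p from 0.00133 to 0.0464). They are not 14 separate hits, since a peak can cross from 1 bin to the next. The 2 ecSE3 bins had the same summit in ecSE3 libraries, at 127796027. The ecSE2 bins from 127400001 and from 127405001 also shared theirs, at 127403785 to 127403818. In 6 of the 14 bins, 2 per perturbation for ecSE1, ecSE2 and ecSE4, all 12 other lists also had a peak. Without the combination 6 bins at the smallest p are needed for any to pass: 6 each did for ecSE2 and ecSE3, while 3 for ecSE1 and 5 for ecSE4 separated the libraries completely and could not pass. In 10 kb bins 4 are needed without the combination, and 4 each passed for ecSE3 and ecSE4 and 0 for ecSE1 and ecSE2. With the 1000 best peaks 0 passed for ecSE4.

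In part of these bins the covered length differed strongly. At 127400001 to 127405000 in CASC8, ecSE2 libraries had 3728 ± 190 bp covered (n = 3) and combination libraries 3974 ± 397 bp (n = 3), against 422 ± 320 bp in the 12 others. At 127725001 to 127730000 in CASC11, ecSE4 libraries had 3262 ± 641 bp and combination libraries 2226 ± 629 bp, against 101 ± 154 bp. At 127230001 to 127235000, by contrast, ecSE1 and combination libraries had 2246 ± 397 bp covered (n = 6) and the others 2322 ± 405 bp (n = 12). Summits in this bin still differed, at 430 to 944 fragments against 233 to 377, not scaled for depth. At 127245001 to 127250000 in CASC21, summits were 3416 to 7673 with ecSE1 or the combination, against 111 to 139 in 3 other lists. At 127740001 to 127745000 over MYC, they were 1071 to 4655 with ecSE4 or the combination, against 65 to 159 in 9 others. The lowest local background, which rises with depth, ran only from 0.501 to 0.872 in COLO320 DM. Depth alone is thus argued against for CASC21 and MYC. Over MYC and 2 kb on each side (127735434 to 127742951), peaks covered 263 ± 283 bp with the vector, 2508 ± 244 bp with ecSE3, 4228 ± 431 bp with ecSE4 and 3966 ± 268 bp with the combination (n = 3 each). LRATD2 (126552443 to 126558478) had 1760 ± 62.6 bp with ecSE2, 778 ± 187 bp with the combination and 0 with the vector. These gene totals are given without a test.

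In PC3 DM the same comparison found 2 bins for ecSE2, 132875001 to 132880000 and 132880001 to 132885000, in TG, the thyroglobulin gene. Both lie outside the window around MYC. They share peaks, since the summits listed for the first in ecSE2 libraries lay just beyond it, at 132880081 to 132880114. Covered length in the second was 2822 ± 207 bp with ecSE2 and 2262 ± 202 bp with the combination (n = 3 each), against 109 ± 232 bp in the 10 others. With ecSE6 2 bins passed, 127795001 to 127800000 at MIR1204 and PVT1 and 126505001 to 126510000 in LOC105375750. PVT1 as a whole had 5730 ± 1475 bp covered with ecSE6 (n = 3) and 691 ± 515 bp with the vector (n = 2). With ecSE1 the bin 133720001 to 133725000, in no gene and 29739 bp from MTND2P7, passed, although 10 of the 10 other lists also had a peak there. It also lies outside the window. Summits there were 369 to 800 fragments high in the 6 ecSE1 and combination lists and 44 to 115 in the others, not scaled for depth. The lowest local background, which rises with depth, averaged 0.205 fragments with ecSE1 and 0.281 with the combination. It averaged 0.296 with the vector, 0.298 with ecSE2, 0.316 with ecSE6 and 0.211 with ecSE7. Greater depth is thus argued against as the source of the higher summits in this bin. The next bin, 133725001 to 133730000, did not pass (Fisher exact test, adjusted p = 0.0603) but had 1963 ± 322 bp covered against 730 ± 240 bp. Each of the 5 bins that passed held 1 of the 100 best peaks in 6 of 6 against 0 of 10 libraries (Fisher exact test over 138 bins, adjusted p from 0.00862 to 0.0172). For ecSE7 pooled with the combination, 0 bins passed and 0 had an unadjusted p under 0.05 (Fisher exact test). Yet 3 bins outside chromosome 8 were in both ecSE7 lists and in no other PC3 DM list, the combination included, and 2 libraries were too few for these to pass. With the combination set aside, 1 bin was likewise in both vector lists and in no single perturbation list. Such bins therefore do not by themselves show an effect of ecSE7. Without the combination 8 bins are needed for any to pass, so 0 did, although 1, 2 and 3 bins still separated the ecSE1, ecSE2 and ecSE6 libraries completely. Within replicate numbers 3 bins are needed and 0 could pass. In 10 kb bins 2 are needed there, and 2 each passed for ecSE2 and ecSE6 and 0 for ecSE1. With the 1000 best peaks 4 are needed, and 0, 2 and 1 separated the libraries.

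**Figure D2:**
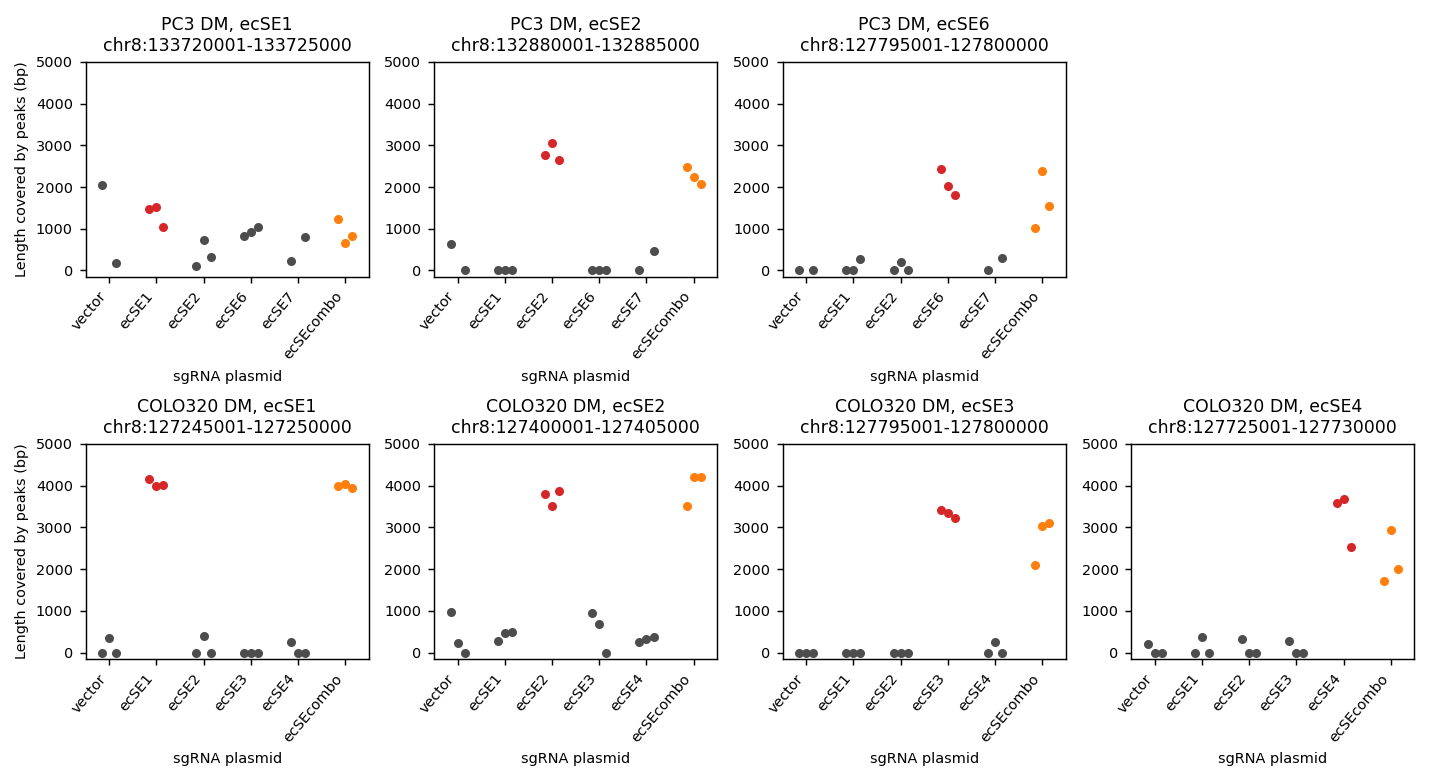
Length covered by peaks in bp in a 5 kb bin of chromosome 8 for each sgRNA plasmid, 1 bin per comparison with a bin past the threshold among the 100 best peaks. Points are libraries, red for the named perturbation, orange for the combination and dark grey for the others; at 127245001 to 127250000 in COLO320 DM the 6 coloured points average 4026 bp and the 12 others 84.6 bp, while at 133720001 to 133725000 in PC3 DM the points overlap. Summits in that PC3 DM bin, not plotted, were 369 to 800 fragments in the 6 coloured libraries and 44 to 115 in the others.

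All perturbed libraries against the vector was a comparison too small to call single bins: in the window 4 bins at the smallest p are needed for 1 to pass in COLO320 DM and 93 in PC3 DM, and among the 100 best peaks 4 and 70. In the window 0 of 132 bins passed in COLO320 DM and 0 of 184 in PC3 DM (Fisher exact test, 1 and 2 with an unadjusted p under 0.05), and among the 100 best peaks 0 passed in either line (5 and 1 unadjusted). Of the 14 gene lists fixed before the data were examined, the imprinted genes of COLO320 DM had a peak in 26.7% ± 12.7 of members per perturbed library (n = 15) and 6.35% ± 2.75 per vector library (n = 3), a rise of 20.3 points (exact permutation, adjusted p = 0.0343). This call was lost with q-values of 1e-05 or less, with lists of equal length, and with an overlap of 500 bp or more. With 1 vector library fewer no single list can pass, since the smallest adjusted p is then 0.206 (exact permutation), and with all libraries it is the 0.0343 found. The MYC locus list stood at 40% ± 16.9 against 16.7% ± 5.77 (exact permutation, adjusted p = 0.0515, n = 15 and 3). In PC3 DM 0 lists passed (exact permutation, 0 with an unadjusted p under 0.05, smallest adjusted p = 0.987), and with 2 vector libraries no single list could, the smallest adjusted p being 0.233.

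Between the lines, 2 genes separated the libraries completely. POU5F1B, inside CASC8 on chromosome 8 (127413447 to 127417224), and PDX1, a pancreatic and duodenal homeobox gene on chromosome 13 (27920000 to 27926313), had a peak in 18 of 18 COLO320 DM and 0 of 16 PC3 DM libraries (Fisher exact test, adjusted p = 2.28e-06). URAD, near PDX1 (27977717 to 27988693), had one in 18 of 18 against 1 of 16, and MYC in 16 of 18 against 5 of 16 (Fisher exact test, adjusted p = 0.0277). These counts pool vector and perturbed libraries. In vector libraries alone MYC had a peak in 2 of 3 against 0 of 2. CDX2, an intestinal homeobox gene between PDX1 and URAD, had one in 4 of 18 against 0 of 16 (Fisher exact test, adjusted p = 0.260). EEF1A1, a translation elongation factor on chromosome 6 (73515750 to 73521032), had one in 18 of 18 against 1 of 16 (Fisher exact test, adjusted p = 1.08e-05), covering 553 ± 253 bp in COLO320 DM.

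Genes with peaks more often in PC3 DM included USP54 (16 of 16 against 1 of 18), HECW1 (16 of 16 against 2 of 18), MDM4, a regulator of p53 (15 of 16 against 0 of 18), and EIF2AK4, a stress kinase of translation (14 of 16 against 0 of 18). LRRTM3 and the zinc finger gene ZNF827 each had one in 15 of 16 against 1 of 18. On the other side stood ELAC1 and EPS8L3 (17 of 18 against 0 of 16), and SLC15A1, KIAA1614 and RDH16 (18 of 18 against 1 of 16). SALL1 and PCMTD2 (17 of 18 against 1 of 16) and MZT1 (18 of 18 against 2 of 16) followed. MCPH1 (16 of 16 against 3 of 18), KAT6B, WWC2 and KLHL28 (15 of 16 against 2 of 18), PIP4P2 and SIK3 (14 of 16 against 1 of 18) were again marked more often in PC3 DM. Adjusted p for the genes of this paragraph was 0.000788 or less (Fisher exact test). A peak anywhere in a gene counted, so long genes can collect scattered peaks, and gene length was not adjusted for. HECW1 ran from 43112647 to 43566001, while MDM4 ran from 204516406 to 204558120 and RDH16 from 56951431 to 56957608. Within 2 kb of either gene end 51 genes passed, 38 more often in COLO320 DM and 13 in PC3 DM (Fisher exact test).

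**Figure D3:**
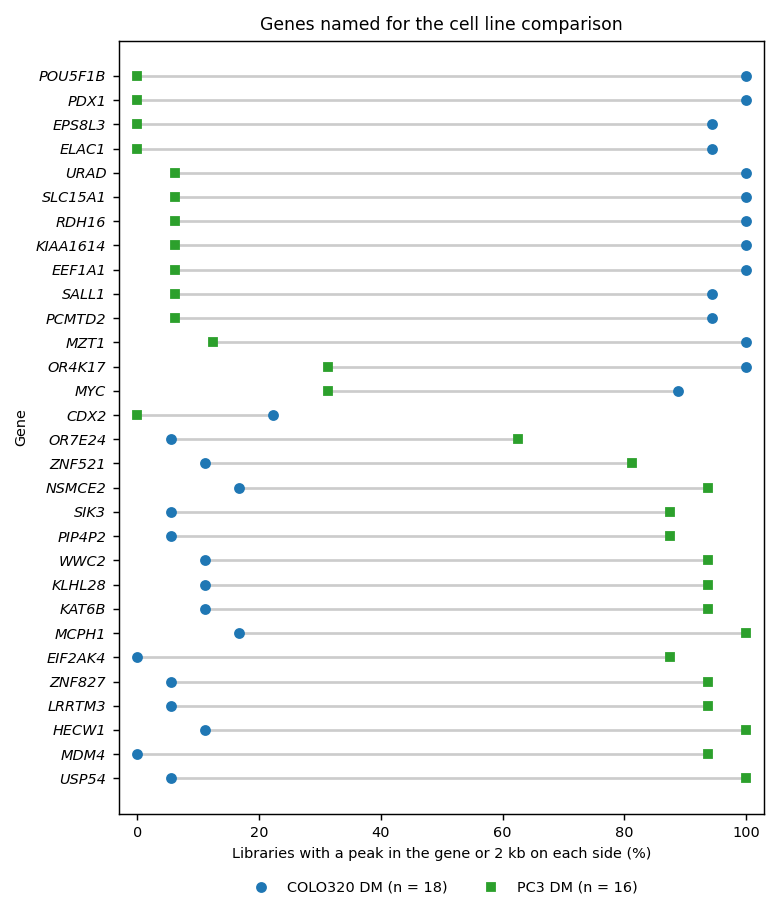
Percentage of libraries with a peak in the gene or 2 kb on each side for the 30 genes named by rule, blue circles for COLO320 DM (n = 18) and green squares for PC3 DM (n = 16). POU5F1B and PDX1 run from 0 to 100%, and CDX2 is the gene shown that did not pass.

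Of 19974 protein-coding genes, 10067 could be tested and 704 passed (Fisher exact test, Benjamini-Hochberg), 126 with peaks more often in COLO320 DM and 578 in PC3 DM. That split depended on how lists were made comparable: 17.9% of the calls lay with COLO320 DM on the lists as deposited, 51.4% with lists of equal length, 61.0% with q-values of 1e-05 or less, 45.3% with an overlap of 500 bp or more and 74.5% around the gene ends. Without COLO320 DM ecSE1 replicate 2 the count was 1491. Line, transfection reagent and experiment went together in these libraries and cannot be separated. Copy number, which was not measured here, cannot be separated from them either. The same holds for the lowest local background, 0.164 to 0.405 fragments in PC3 DM and 0.501 to 0.872 in COLO320 DM libraries.

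Over all protein-coding genes, 16.6% ± 7.93 had a peak per COLO320 DM library (n = 18) and 25.1% ± 8.95 per PC3 DM library (n = 16). Lists were not tested against this background, which is also lower in COLO320 DM. By list, the COLO320 DM amplicon partners had a peak in 42.4% ± 14.9 of members per COLO320 DM library (n = 18) and 23.4% ± 11.1 per PC3 DM library (n = 16), a difference of 18.9 points (permutation test, adjusted p = 0.00812). Of the 6 members tested, PDX1 and URAD were called, and 2 also when adjusted over the list alone. Mesenchymal genes stood at 17.8% ± 12.5 in COLO320 DM and 31.7% ± 13.2 in PC3 DM (-13.9 points, permutation test, adjusted p = 0.0364), with 0 of 12 tested members called over all genes or adjusted over the list alone. With lists of equal length that difference was 0.231 points and the call was lost. The other 12 lists did not pass. Protocadherin clusters stood at 33.0% ± 25.0 in COLO320 DM against 54.0% ± 20.3 in PC3 DM, imprinted genes at 23.3% ± 13.9 against 35.1% ± 12.0 and neuroendocrine genes at 10.7% ± 11.0 against 21.7% ± 13.4 (permutation test, adjusted p = 0.0539 for each). Leaving out single libraries gave from 1 to 9 lists past the threshold, 9 without COLO320 DM ecSE1 replicate 2.

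Zinc finger genes had a peak in 51.0% ± 8.38 and 55.6% ± 9.17 of members, with 4 called more often in COLO320 DM and 11 in PC3 DM of 295 tested, ZNF827 and ZNF521 among the latter. Adjusted over the list alone, these counts were 4 and 9. Olfactory receptors stood at 7.81% ± 7.53 and 13.3% ± 7.99, with OR4K17 marked more often in COLO320 DM (18 of 18 against 5 of 16) and OR7E24 in PC3 DM (1 of 18 against 10 of 16), and 3 and 2 called when adjusted over the list alone. The MYC locus list stood at 36.1% ± 17.9 and 41.3% ± 20.9, with MYC and POU5F1B called for COLO320 DM and NSMCE2 for PC3 DM (3 of 18 against 15 of 16), and 2 and 4 members when adjusted over the list alone. Prostate lineage genes stood at 13.7% ± 9.56 and 21.3% ± 13.8, intestinal lineage genes at 17.0% ± 10.5 and 21.3% ± 12.9, and haematopoietic genes at 8.89% ± 7.23 and 9.17% ± 8.73. Housekeeping genes stood at 6.39% ± 4.79 and 10.0% ± 8.94, HOX clusters at 2.71% ± 4.53 and 5.93% ± 4.84, and cancer testis genes at 3.66% ± 3.61 and 4.19% ± 2.93. With lists of equal length, housekeeping genes passed in the opposite direction, with a share 4.03 points higher in COLO320 DM (permutation test, n = 18 and 16, adjusted p = 0.00014, from 0.00014 to 0.861 over 41 alternatives). Before adjustment this was the smallest p the resamples can give. On the lists as deposited EEF1A1 had a peak in 18 of 18 COLO320 DM and 1 of 16 PC3 DM libraries. No other housekeeping gene had one in more than 1 COLO320 DM list, so the housekeeping shift rests mainly on EEF1A1. The difference also turned, without passing, for the MYC locus, prostate, intestinal, haematopoietic and cancer testis lists. Around either gene end the MYC locus list passed in the opposite direction, 18 points higher in COLO320 DM (permutation test, adjusted p = 0.00168, from 0.00168 to 1). With an overlap of 500 bp or more the haematopoietic genes did, 4.40 points higher (permutation test, adjusted p = 0.0122, from 0.0122 to 1). No list was enriched among the called genes after adjustment (Fisher exact test, smallest adjusted p = 0.0632, for the amplicon partners).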

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

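The tests of the U6 peak and all but 1 each of the tests at EEF1A1 and before MYC were chosen after the results were seen; the copy number test at EEF1A1 and the test of neighbouring bins were written before, but what each was allowed to decide was narrowed after, the second to bins that could move in either direction. The combination was set against the vector in both lines, and on the lists as deposited the share of peaks around MYC moved in opposite directions. All 3 combination libraries of PC3 DM lay above the vector mean and all 3 of COLO320 DM below it, by a mean difference of -0.349 points in COLO320 DM. That value turned positive with lists of equal length (0.323), with the 100 best peaks (3.33) and without COLO320 DM vector replicate 2 (0.207). The difference between the lines, tested in the report, was -0.380 points (permutation, p = 0.665). No group had 4 or more libraries, so no test for single libraries far from their group was made.

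A peak beside RNU6-1, a U6 gene on chromosome 15 (67839939 to 67840045), stood between 67840031 and 67840307 in 32 of 34 lists, vector libraries included, and came first by q-value in 14 of 14 PC3 DM and 10 of 18 COLO320 DM lists that had it. The 2 lists without it held no peak shorter than 285 and 293 bp, more than the 248 to 277 bp of this peak, so its absence there shows nothing. Its edges varied with an SD of up to 4.89 bp, against a median smaller SD of 27.6 bp at 16 other regions, the lowest being 1.75 bp. Such fixed edges are what reads from a U6 promoter on the transfected sgRNA plasmid would give. Marked chromatin at U6 genes in general is argued against, since 0 lists had a peak at any of the other 4. Marked chromatin at the chromosomal RNU6-1 gene alone stays open, since 0 libraries had no sgRNA plasmid. The plasmid promoter may therefore be the source.

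The peak at EEF1A1 in COLO320 DM lay between 73520041 and 73521204 in 18 of 18 lists. Tagging of open promoters in general is argued against, since 0 of 19 other housekeeping genes had a peak in as many as 50% of the COLO320 DM lists. More copies of the EEF1A1 locus stays open: the 100 kb on each side had 0.611 ± 0.850 peaks per list against 1.13 ± 1.31 in PC3 DM, opposite to its prediction but within chance (difference -0.514, permutation p = 0.245, n = 18 and 16). Reads from an EEF1A1 promoter in a construct carried by the cells also stay open: 100% of the covered length lay within 1.2 kb of the higher gene end, while the edges varied with an SD of 295 bp.

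In the bin before MYC, 127730001 to 127735000, no peak was listed in 6 of 6 ecSE4 and combination lists of COLO320 DM. The local background of peaks nearby was 126 to 1305 fragments in these lists and 22.7 to 88.5 in the others, not scaled for depth. Local background raised by the neighbouring signal may hide peaks: of 11 summits in the other lists, 101 to 160 fragments high, 0 would have reached the threshold over the lowest of those backgrounds. Less of the mark in the bin itself cannot be told apart from this, since 0 of the 6 lists gave a summit there. A loss beside every region with added signal stays open: of 10 neighbouring bins, 4 had no peak in any other list and could not be lower, and of the remaining 6, 3 had peaks in a smaller share of lists and 3 in a larger one (mean 1.67 points). The lower call at CASC11 does not by itself show less of the mark.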

How the results depend on the processing

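The settings with the 50, 100, 200, 300 or 1000 best peaks, the 10 Mb window, genes without flanks, gene ends and long lists left out were chosen after the results were seen. Of 3843 alternative values for 133 results, 3486 kept direction and side of the threshold or stayed within bounds; of single genes, bins or lists, 97 fell below the threshold and 59 rose above it. Where a result changed, the cause was not tested unless given. Differences from the vector in the share of peaks around MYC turned for PC3 DM ecSE1 with covered bp (0.0224) and within replicate numbers (0.0114), for PC3 DM ecSE2 in a 1 Mb window (0.00422), and with lists of equal length for PC3 DM ecSE7 (-0.0292), COLO320 DM ecSE1 (0.00710), the COLO320 DM combination (0.323) and the difference between the lines (0.204). With the 100 best peaks ecSE7 had -0.5, the COLO320 DM combination 3.33 and the difference between the lines 1.67. Leaving out single libraries gave -0.0468 to 0.0219 for PC3 DM ecSE1, -0.0219 to 0.00778 for ecSE2, -0.00463 to 0.0958 for ecSE7, -1.03 to 0.0201 for COLO320 DM ecSE2, -0.839 to 0.207 for its combination, -0.870 to 0.177 for the difference between the lines, and -0.271 to 0.205 for log10 peaks in PC3 DM. Bins around MYC, for PC3 DM ecSE1, ecSE2 and ecSE6 (0 each as reported), numbered 3, 2 and 2 with the 100 best peaks and 10 Mb window; ecSE6 had 2 with an overlap of at least 500 bp and with the 100, 300 and 1000 best peaks. For COLO320 DM ecSE1, ecSE2 and ecSE4 (0, 1 and 1) they numbered 4, 3 and 5 with the 100 best peaks in either window. For ecSE1, ecSE2, ecSE3 and ecSE4 they numbered 2, 2, 4 and 4 with the 300 best peaks, 1000 best peaks gave ecSE1 2, ecSE2 2 and ecSE4 0, and equal list length and an overlap of at least 500 bp gave ecSE1 1. For ecSE2, ecSE3 and ecSE4 (1, 2 and 1) they numbered 0, 1 and 0 in the 10 Mb window and in the replicate block (tests within replicate numbers), 0, 0 and 0 with ecSEcombo libraries left out, where too few libraries remain for fewer than 5 bins to pass, and 0 to 1, 1 to 2 and 0 to 1 without single libraries; 10 kb bins gave ecSE3 1 and ecSE4 0, and ecSE4 had 0 with lists over 100000 peaks left out. Replicate numbers did not pair libraries (median r -0.0149 in PC3 DM and 0.00766 in COLO320 DM). Genome-wide bins among the 100 best peaks, for PC3 DM ecSE1, ecSE2 and ecSE6 (1, 2 and 2), numbered 0 each with the 1000 best peaks, in the replicate block and with ecSEcombo libraries left out, where fewer than 4, 3 and 8 bins cannot pass; ecSE1 had 3 with the 50 best peaks, 0 with the 300 best peaks and in 10 kb bins, and 1 to 2 without single libraries. For COLO320 DM ecSE1, ecSE2, ecSE3 and ecSE4 (4, 3, 2 and 5) they numbered 2, 1 and 4 for the first 3 with the 200 best peaks, 2, 1, 4 and 3 with the 300 best peaks, 2 for ecSE1 and 0 for ecSE4 with the 1000 best peaks, 0 for ecSE1 and 1 for ecSE3 in 10 kb bins, and 0, 6, 6 and 0 with ecSEcombo libraries left out, where fewer than 6 cannot pass. The bin 127810001 to 127815000 went from 75 to -25 points for ecSE4 with the 300 best peaks. Genes differing between the lines (704) numbered 464 with -log10 q of at least 5, 51 within 2 kb around either gene end, 1136 with lists over 100000 peaks left out, and 510 to 1491 without single libraries. Lists differing between the lines (2) numbered 1 with -log10 q of at least 5, 4 with equal list length, 5 in the replicate block, 7 with lists over 100000 peaks left out and 1 to 9 without single libraries. Lists differing between perturbed and vector libraries of COLO320 DM (1) numbered 0 with -log10 q of at least 5, equal list length, an overlap of at least 500 bp, 2 kb around either gene end and the replicate block, and 0 to 2 without single libraries; in the replicate block or without a vector library no single list can pass. List differences between the lines turned positive with -log10 q of at least 5 for MYC locus (4.93), cancer testis (0.47), housekeeping (0.590), intestinal (1.71) and haematopoietic genes (1.62). With equal list length they did for MYC locus (5.76), cancer testis (0.00789), housekeeping (4.03, past the threshold, mainly through EEF1A1), prostate (0.926), intestinal (1.81), mesenchymal (0.231) and haematopoietic genes (2.36). With an overlap of at least 500 bp they did for zinc finger (3.47), olfactory (0.458), cancer testis (0.655), housekeeping (2.15), intestinal (1.62) and haematopoietic genes (4.40, past the threshold). Around either gene end they did for MYC locus (18, past the threshold), housekeeping (2.12), intestinal (1.90) and mesenchymal genes (2.5). Haematopoietic genes had 1.81 for the gene without flanks and -1.32 to 0.889 without single libraries. Depth was not separated from list length, since read totals are unknown and the lowest local background was not used to adjust for it.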

Other observations

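The combination test and the setting with the 100 best peaks were chosen after the results were seen, and the tests by splits of the libraries were written before. In place of the real groups, 100 splits of the same libraries into groups of the same sizes were tried, the real one included. The 704 genes that differed between the lines were reached in 1 of 100 splits, the real one, the highest other giving 0. Random splits mix the lines, so this shows only that libraries of the 2 lines differ, whatever the source. It does not show that single genes are free of chance, and the count ran from 51 to 1491 between settings. Around MYC in COLO320 DM, ecSE2 (1 bin) was reached in 3 of 100 splits and ecSE4 (1 bin) in 2, the highest other giving 1 in both, and ecSE3 (2 bins) in 1, the highest other giving 0. Among the 100 best peaks each real count was reached in 1 of 100 splits: for ecSE1 (1), ecSE2 (2) and ecSE6 (2) in PC3 DM and ecSE1 (4) and ecSE3 (2) in COLO320 DM the highest other was 0, for COLO320 DM ecSE4 (5) it was 1 and for ecSE2 (3) it was 2. Random splits thus rarely reached these counts, within the setting each was made in and without adjustment over the comparisons. For ecSE2 and ecSE4 around MYC, chance is not excluded. Other splits gave the same count there, and both calls were lost without most single libraries. Splits within the 100 best peaks cannot cover the choice of that setting after the data were seen. For comparisons with a count of 0 the splits decide nothing, since all 100 reach 0 by construction, the highest other giving 0: this holds around MYC for the 4 single perturbations of PC3 DM, ecSE1 and all perturbed libraries of COLO320 DM, over the whole genome for every comparison tried, and among the 100 best peaks for PC3 DM ecSE7 and all perturbed libraries of COLO320 DM (Fisher exact test, unadjusted counts in the report).

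A hypothesis tested here was that the combination holds the same elements as the single perturbations. Bins with 1 of the 100 best peaks in every list of 1 single perturbation and in no other list outside the combination numbered 29, and 57.5% of combination lists had them, against 6.11% for 60 bins shared by 3 lists of mixed groups. Neighbouring bins can hold the same peak, so the 29 bins are not all separate regions. The combination may therefore hold most of these elements, within that limit. All combination lists had 1 of the 1 ecSE1, 2 of the 2 ecSE2 and 2 of the 3 ecSE6 bins in PC3 DM, and 2 of 3, 2 of 6, 2 of 6 and 5 of 5 for ecSE1, ecSE2, ecSE3 and ecSE4 in COLO320 DM. For ecSE7 the 3 bins lay outside chromosome 8 and no combination list had them, so for this element the hypothesis stays open.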
